A study of Equus caballus with 49 samples.

How the data were processed

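Peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes that a density gradient separates from whole blood, were taken from 20 horses with naturally occurring osteoarthritis (OA) and 29 healthy horses (Control). The series design text gives 39 control horses for mRNA sequencing, 10 more than have counts here, and the reason is not given in the sources used here. Each library came from 1 horse. PolyA RNA was sequenced from libraries made with an ABclonal mRNA kit, per the labels' protocols. The deposited table holds whole-number read counts per gene, not normalized, for 29698 genes and 49 columns, and each column name matched 1 sample. The submitters' processing notes list Partek, cutadapt 1.12, STAR 2.7.3a, HTSeq 0.11.0 and limma 3.64.1 without saying what each did. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap or that share reads with a near-identical copy therefore carry uncertain counts. The fecal, microbial and metabolite measurements of the same study were not analysed here.

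In 7 genes the deposited counts of controls 78, 80, 81 and 84 were replaced by a spreadsheet error, and these genes were left out. They held at most 0.00519% of the counts in any of the other 45 columns. Of the remaining 29691 genes, 22663 had a count in at least 1 library. Total counts ran from 20.9 to 43.5 M (mega counts) per library, with a median of 26.2 M. The genes tested held at least 99.9% of the counts of each library. No pair looked like 1 library counted again: over all 1176 pairs the lowest chi-square per gene was 20.7, where sampling noise alone gives about 1. The lowest pair was OA 72 and OA 73, and the median was 132. Separate libraries made from 1 horse would not be found this way.

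Groups were taken from the sample titles. The horse numbers in the titles do not pair OA with Control animals, so no block was fitted, and the labels give no batch, sex, age or breed. The control numbers fall into the ranges 1 to 16 (12 horses), 29 to 45 (13 horses) and 78 to 84 (4 horses), while all OA numbers lie between 50 and 76. The columns of the deposited table stand in 3 stretches, and within each the horse numbers run in alphabetical order. Set 1 holds 14 OA and 15 Control libraries, set 2 holds 6 OA and 10 Control libraries, and set 3 holds the 4 controls numbered 78 to 84. The library names in the labels keep each of these sets together as well. No label calls the sets a batch, and they were used as a possible batch because libraries of the same group differed between them.

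Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, which left 13920, library sizes were scaled by TMM factors, and OA was compared with Control by the quasi-likelihood test, two-sided, over all 49 libraries and with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the log2 fold change divided by the square root of the F statistic. The same test compared controls numbered 29 to 45 with controls numbered 1 to 16. These tests, the principal components, the comparison of total counts and of the share of the 10 most abundant genes, and 16 of the 24 alternatives for the count of OA against Control were fixed before the data were examined; all uses of the column sets and the other library measures were added afterwards. With the sets as a covariate, set and group entered the model together. The difference of the OA effect between sets 1 and 2 was tested as their interaction. Principal components were computed on log2 CPM (prior count 2) of the 500 most variable genes. Component scores and library measures were compared by two-sided permutation tests with 100000 resamples. Comparisons within set 2, with 6 against 10 libraries, used exact permutation tests.

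The rule for named genes and the fixed lists of pathway and cell type genes needed gene symbols. The table gives identifiers only, the files do not pair them with names, and 0 of the identifiers matched the reference table of 39335 genes. The pathway lists, the cell type marker scores and the shares of haemoglobin, mitochondrial and ribosomal protein genes were therefore not computed, and no gene is named. In their place the 2 genes with the smallest p in each direction are given by identifier.

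The test was checked on simulated data. Counts were drawn for the 13920 genes from the real means, dispersions and library sizes. For OA against Control, edgeR recovered 55.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold. It made 16 false calls, 9% of its calls against a threshold of 0.05, and no calls where no gene was changed. Only means, dispersions and library sizes were taken from the data. The simulation therefore cannot show how often real libraries give false calls. Of 100 splits of the real libraries, the real one included, 96 gave no call. The highest count besides the real one was 1511. For the ranges of controls the recovered shares were 38.8%, 63.6% and 98.4%. With the sets as a covariate, and 2982 simulated genes moved 2-fold by the set, the shares for OA against Control were 50%, 89.6% and 100%, with 8 false calls. Alternatives included DESeq2 1.42.0, limma 3.58.1 (voom), rank-sum tests, other scalings and filters, surrogate variables from sva 3.50.0, subsets of the controls, and leaving out each library.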

Results

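The study asked how the blood cells of horses with osteoarthritis, a degenerative joint disease, differ from those of healthy horses. Gene expression was measured by polyA RNA sequencing in PBMC of 20 OA and 29 Control horses. The series title ties the disease to aging, but the ages of the horses are not given in the sources used here. Total counts averaged 26.5 ± 3.28 M (mega counts; SD, n = 20) in OA and 26.8 ± 5.31 M (SD, n = 29) in Control libraries. Between 12935 and 17394 genes had a count in a library. The groups did not differ past the threshold in any of the 5 library measures compared. These were the total count, the number of genes detected before and after thinning each library to 20000000 counts, the share of the 10 most abundant genes and the scaling factor (adjusted p = 0.852 or above, two-sided permutation tests). Fewer than 15000 genes were detected in 7 libraries, namely controls 06, 07, 09 and 29 and OA horses 52, 60 and 65.

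Many genes differed in the PBMC of OA horses, in both directions and mostly by small amounts. Of 13920 genes tested, 1686 were higher and 1772 lower in OA than in Control (3458 genes, 24.8%, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without adjustment, 4997 genes had p under 0.05. Among the called genes, 661 differed by at least 2-fold, 290 of them higher and 371 lower in OA. At least 4-fold differences were reached by 40 genes that rose and 44 that fell. At the other end, 935 higher and 974 lower genes differed by less than 1.5-fold, and the median absolute log2 fold change of called genes was 0.54. The median over all tested genes was 0.01. Calls were spread over the range of abundance. They made up 14.7% of the 1317 genes with a mean under 1 CPM, 25.5% of the 3289 genes at 1 to 8 CPM, 25.9% of the 5905 genes at 8 to 64 CPM and 26.3% of the 3409 genes above 64 CPM. In 0 genes did the values of all 20 OA libraries lie apart from those of all 29 controls.

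The gene with the smallest p among those that rose was ENSECAG00000042978. Its level was 204 ± 48.1 CPM (SD, n = 20) in OA and 103.9 ± 23.4 CPM (SD, n = 29) in Control, a log2 fold change of 0.97 (SE 0.09, adjusted p = 3.48e-11, edgeR). All 20 OA libraries lay above the control median, and 15 lay above every control. A larger rise was seen for ENSECAG00000006595, from 2.49 ± 1.16 CPM (SD, n = 29) in Control to 17.6 ± 15.8 CPM (SD, n = 20) in OA, a log2 fold change of 2.82 (SE 0.28, adjusted p = 1.75e-10, edgeR). Here 19 of 20 OA libraries lay above the control median. The strongest fall by p was in ENSECAG00000021201, at 1.54 ± 0.724 CPM (SD, n = 20) in OA against 14.3 ± 11.6 CPM (SD, n = 29) in Control. It fell by 3.21 on the log2 scale (adjusted p = 1.30e-11, edgeR), and all 20 OA libraries lay below the control median. The gene ENSECAG00000010347 fell by 1.82 on the log2 scale (SE 0.16, adjusted p = 1.30e-11, edgeR), from 52.6 ± 18.0 CPM (SD, n = 29) to 14.9 ± 5.45 CPM (SD, n = 20). All 20 OA libraries lay below the control median for this gene too. Against the 4 controls numbered 78 to 84 alone, both rising genes lost the call, with log2 fold changes of 0.67 (adjusted p = 0.0781, edgeR) and 2.50 (adjusted p = 0.0727, edgeR).

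The column sets of the table differed from each other by more genes than the groups did. With the group in the model, 3688 genes were higher and 3540 lower in set 2 than in set 1 (7228 genes, edgeR, adjusted p under 0.05). The same comparison gave 6351 genes among the control libraries alone and 3802 among the OA libraries alone. Neither count separates the set from the horse number. Of the controls, 12 of 15 in set 1 were numbered 29 to 45. In set 2, 9 of 10 were numbered 1 to 16. Set 2 held OA 52, 55, 56, 57, 60 and 65, and set 1 held OA 50 and horses numbered 61 to 76. OA 52, 60 and 65 had fewer than 15000 genes detected. Without the 7 such libraries of both groups, 5768 genes differed with the group in the model. Libraries of set 2 had total counts of 31.0 ± 4.40 M (SD, n = 16), against 24.5 ± 3.02 M (SD, n = 29) in set 1 (p = 1e-05, the smallest that 100000 permutations can give). Fewer genes were detected in set 2, 15739 ± 1393 (SD, n = 16) against 16465 ± 596 (SD, n = 29) (permutation p = 0.017). In set 2, 5 libraries had 12935 to 14687 genes detected, and the others had 15709 to 16951. In set 1, controls 06 and 07 had 14897 and 14927, and the others had 15469 to 17394. Outside the low libraries the ranges of the sets overlapped, so the lower mean is not a trait of all set 2 libraries. This comparison was not repeated without the low libraries. The share of counts in the 10 most abundant genes was 6.88% ± 1.21 (SD, n = 16) in set 2 and 5.41% ± 0.535 (SD, n = 29) in set 1 (permutation p = 1e-05). These 3 differences between sets were tested without adjustment for each other.

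Both sets 1 and 2 held horses of both groups, so OA and Control were compared within them. With the sets as a covariate, 2399 genes were higher and 2388 lower in OA (4787 genes, edgeR), and 3345 of the 3458 genes called without the covariate were called in the same direction. Within set 1, with 14 OA and 15 Control libraries, 2752 genes were higher and 2817 lower in OA (5569 genes, edgeR). Within set 2, with 6 OA and 10 Control libraries, 118 genes were higher and 63 lower (181 genes, edgeR), and 2627 genes had an unadjusted p under 0.05. When 6 OA and 10 Control libraries were drawn at random from set 1, 20 draws gave between 1325 and 4380 genes. Without the 5 libraries of set 2 with fewer than 15000 genes detected, 3 OA and 8 Control libraries remained and 2249 genes were called. The count of 181 also moved with single libraries. It fell to 43 without control 10, 44 without control 08, 51 without control 04, 59 without control 05, 61 without control 15, 65 without OA 56, 66 without OA 60, 77 without control 16, 78 without control 01, 84 without control 14 and 91 without OA 65. It rose to 459 without OA 57 and to 1005 without control 09. Set 3 held controls only and gives no such comparison.

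The calls of sets 1 and 2, which share no library, overlapped in the same direction for 88 higher and 39 lower genes, and 1 gene was called in opposite directions. Independent lists of these lengths among the 13487 genes tested in both would share 23.8 higher and 12.3 lower genes. Across these genes the log2 fold changes of the sets correlated with r = 0.502, where genes are not independent replicates. With the OA and Control labels of set 2 shuffled, r ran from -0.461 to 0.464 over the other splits. Of the 5501 genes called in set 1 and tested in both, 73.5% had the same sign in set 2, against 23.3% to 76.8% with the shuffled labels, and 4 of 100 splits, the real one included, gave as high a share. Their median absolute log2 fold change was 0.48 in set 1, where they were chosen, and their median log2 fold change in the set 1 direction was 0.26 in set 2. The OA effect itself differed between the sets for 669 genes (edgeR interaction test, adjusted p under 0.05), and for 1684 genes without the 7 libraries with fewer than 15000 genes detected. The sets also differ in their controls: 12 of the 15 in set 1 were numbered 29 to 45, and 9 of the 10 in set 2 were numbered 1 to 16. This test cannot separate a different OA effect from a difference between these ranges of controls.

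The 4 genes given above kept their direction in both sets, which their choice by p over all libraries, those of both sets included, favours. ENSECAG00000042978 was at 217 ± 50.6 CPM (SD, n = 14) in OA and 101.5 ± 20.6 CPM (SD, n = 15) in Control within set 1, and at 173 ± 21.2 CPM (SD, n = 6) and 98.1 ± 15.2 CPM (SD, n = 10) within set 2. It passed the threshold in each (adjusted p = 1.78e-08 and 0.00596, edgeR). ENSECAG00000006595 was at 22.5 ± 16.6 CPM (SD, n = 14) in OA and 2.10 ± 1.08 CPM (SD, n = 15) in Control in set 1. In set 2 it was at 6.17 ± 3.45 CPM (SD, n = 6) and 2.84 ± 1.31 CPM (SD, n = 10), which did not pass (adjusted p = 0.22, edgeR). Without the 5 libraries of set 2 with fewer than 15000 genes detected it passed, with a log2 fold change of 1.56 (adjusted p = 0.00317, edgeR). Its effect differed between the sets (adjusted p = 0.0149, edgeR interaction test). ENSECAG00000021201 passed in set 1 (adjusted p = 2.56e-09, edgeR) and in set 2 (adjusted p = 0.0165, edgeR), with a smaller fall in set 2 (adjusted p = 0.0407, edgeR interaction test). ENSECAG00000010347 passed in set 1 (adjusted p = 8.15e-11, edgeR), and in set 2 it stood at 16.8 ± 8.46 CPM (SD, n = 6) in OA and 40.7 ± 14.8 CPM (SD, n = 10) in Control (adjusted p = 0.0711, edgeR). Without the same 5 libraries it fell by 1.19 on the log2 scale in set 2 and passed (adjusted p = 0.0155, edgeR). For this gene and for ENSECAG00000042978 the interaction did not pass (adjusted p = 0.126 and 0.333, edgeR).

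**Figure D1:**
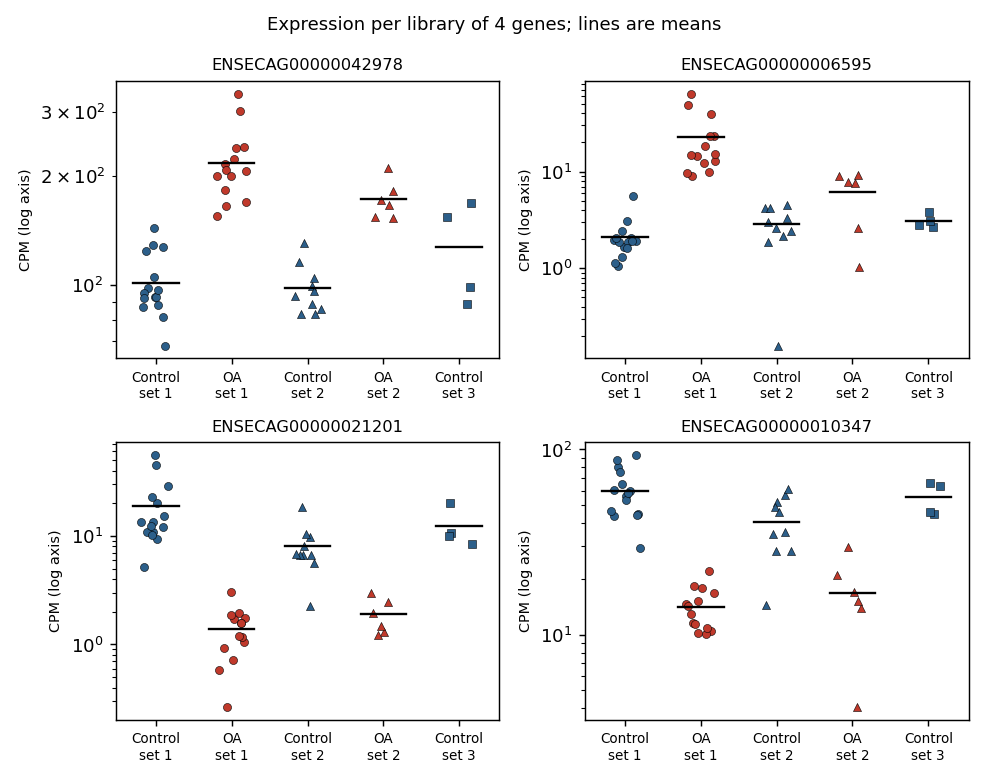
Each point is 1 library, with CPM on a log axis, split by group and column set, and the line is the mean. In set 1 the 14 OA libraries lie apart from the 15 controls for all 4 genes, while in set 2 they overlap for ENSECAG00000006595, ENSECAG00000021201 and ENSECAG00000010347.

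**Figure D2:**
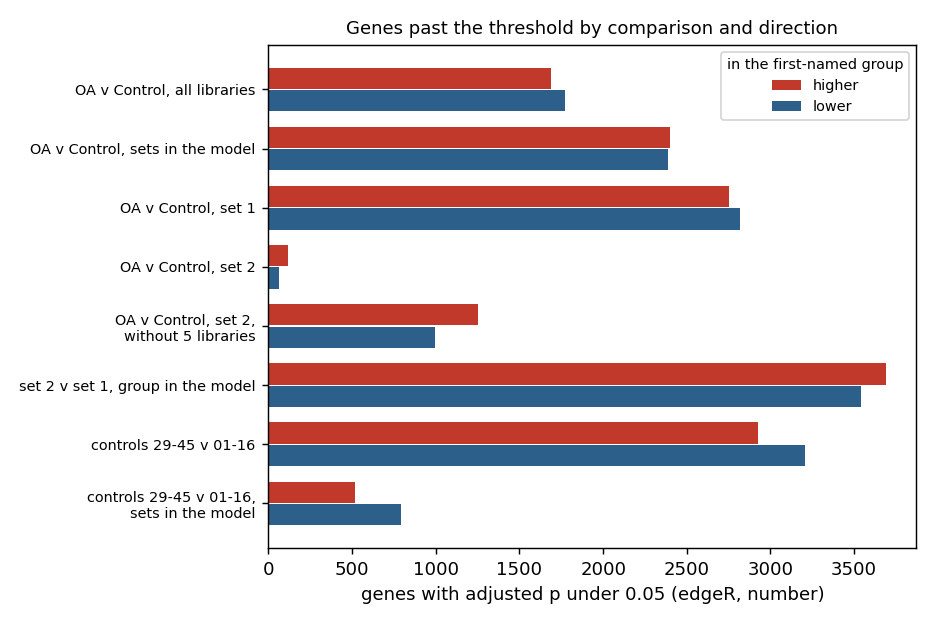
Bars show the number of genes with an adjusted p under 0.05 in edgeR, higher or lower in the first-named group of each comparison. Set 2 against set 1 gives 7228 genes and OA against Control gives 3458, or 4787 with the sets in the model.

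The mean scores of OA and Control libraries differed on 2 of the first 5 principal components of the most variable genes. Below, a component is said to separate the groups where these means differed. Over all 49 libraries the scores of the groups overlapped on both components. Among the 500 most variable genes, the first component held 21.1% of the variance, with scores of 15.9 ± 12.9 (SD, n = 20) in OA and -11.0 ± 10.9 (SD, n = 29) in Control (adjusted p = 5e-05, permutation test over 5 components). The second held 11.9%, with scores of 7.92 ± 15.7 (SD, n = 20) and -5.46 ± 7.90 (SD, n = 29) (adjusted p = 6.25e-04, permutation test). Components 3 to 5 did not separate the groups (adjusted p = 0.38 or above). With all tested genes the first component, with 28.6% of the variance, did not separate the groups (adjusted p = 0.105, permutation test), and the second, with 10.2%, did (adjusted p = 5e-05, permutation test). Within set 1 the first component separated OA from Control (11.3 ± 5.12, n = 14, against -18.6 ± 7.06, n = 15, adjusted p = 5e-05, permutation test). It did so within set 2 as well (26.6 ± 19.2, n = 6, against -1.80 ± 8.10, n = 10, adjusted p = 0.00208, exact permutation test), though controls 09 and 29 scored above OA 57 (8.94). In set 2 the highest scores of each group belonged to libraries with fewer than 15000 genes detected, from 25.2 to 59.7 for OA 52, 60 and 65 and 13.2 and 10.5 for controls 09 and 29. Without these 5 libraries the scores were 12.6 ± 4.73 (SD, n = 3) and -5.21 ± 4.16 (SD, n = 8) (exact permutation p = 0.00606, the smallest that these numbers allow). The second component separated the groups in set 1 (adjusted p = 5e-05, permutation test) and not in set 2 (adjusted p = 0.703, exact permutation test). In set 2 the OA libraries had 14782 ± 1620 genes detected (SD, n = 6) and the controls 16313 ± 894 (SD, n = 10), a difference that did not pass after adjustment over the 10 measures compared within sets (p = 0.0296, adjusted p = 0.074, exact permutation test).

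**Figure D3:**
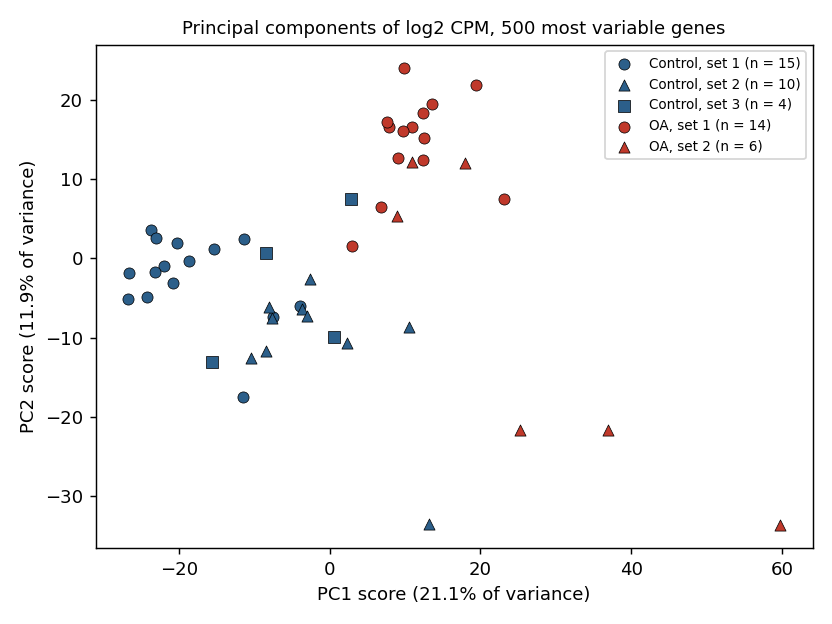
Scores of each library on the first and second principal components of log2 CPM, which hold 21.1% and 11.9% of the variance; colour gives the group and shape the column set. OA libraries lie on average to the right of the controls of their own set, with mean first-component scores of 11.3 against -18.6 in set 1 and 26.6 against -1.80 in set 2.

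Controls drawn from different number ranges were compared as a measure of how far healthy horses differ among themselves. Between controls 29 to 45 (n = 13) and controls 1 to 16 (n = 12), 2925 genes were higher and 3207 lower in the former (6132 genes, edgeR, adjusted p under 0.05). These ranges lie mostly in different column sets: 9 of the 12 controls numbered 1 to 16 were in set 2, and 12 of the 13 numbered 29 to 45 were in set 1. With the sets as a covariate, 1308 genes differed between the ranges, and within set 1, with 3 against 12 libraries, 2772 did. Of these 3 controls, 06 and 07 had fewer than 15000 genes detected, and without such libraries 469 genes differed between the ranges with the sets as a covariate, a fit in which control 03 alone stands against 12 controls of set 1. OA differed from controls 1 to 16 in 2363 genes, from controls 29 to 45 in 5332 genes and from the 4 controls numbered 78 to 84 in 252 genes (edgeR). Of the 4 genes given above, only ENSECAG00000021201 differed between controls 29 to 45 and controls 1 to 16 (log2 fold change 1.01, adjusted p = 0.0181, edgeR). Its mean in OA, 1.54 CPM, was below that of both ranges, 19.4 ± 15.5 CPM (SD, n = 13) and 9.51 ± 3.74 CPM (SD, n = 12).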

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

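Settings that use the column sets, the number of genes detected, the removal of the controls numbered 78 to 84 or an equal weighting of the control ranges were chosen after seeing the data, as were all tests between the sets and the runs of the control ranges without 1 library. The count of 3458 genes for OA against Control stayed within 1.5 times under 16 of 24 settings, DESeq2, voom, the rank-sum test and every other scaling and filter among them. This compares the number of genes, not which genes were called. Against controls 1 to 16 only, 2363 genes were called, and 1583 of them were among the 3458 in the same direction. Against controls 29 to 45 only, 2763 of 5332 were. The count was 5393 with voom quality weights, 6734 with 8 surrogate variables, 5332 against controls 29 to 45 only, 252 against the 4 controls numbered 78 to 84 only, 5569 in set 1, 181 in set 2 and 2249 in set 2 without its 5 libraries of fewer than 15000 genes. Requiring an absolute log2 fold change of at least 1 left 661, by construction. For the 181 genes of set 2, 20 random draws of as many libraries from set 1 gave 1325 to 4380 genes. This argues against the number of libraries alone as the source of the low count. Without single libraries the count of 181 ran from 43 to 1005. For the other counts the cause was not tested. Leaving out 1 library gave 3137 (without OA 56) to 4067 (without control 09) genes. The 6132 genes between controls 29 to 45 and 1 to 16 became 1308 with the sets as a covariate, 469 with that covariate and without the 4 of these libraries of fewer than 15000 genes (control 03 against 12), and 2772 in set 1 only. Without 1 library they ranged from 5723 to 6872. The 7228 genes between sets 1 and 2 became 3802 in the OA libraries only, which are fewer. The 669 genes whose OA effect differed between sets became 1684 without the 7 libraries of fewer than 15000 genes, and the cause was not tested. With all tested genes, the mean scores of the groups differed on 1 component in place of 2, and the first was the one lost. No direction of the 4 genes given by identifier reversed under 23 settings, 19 of them added for these genes after seeing the data, or without any 1 library. Their choice by p over all libraries favours this. The call was lost under 2 settings for ENSECAG00000006595 and under 1 setting each for ENSECAG00000042978 and ENSECAG00000010347. Not run, for want of gene symbols: all alternatives for the gene lists and marker scores, marker scores or XIST as covariates, and scaling without haemoglobin, mitochondrial and ribosomal protein genes. At the real depth and number of libraries 55.2% of simulated 1.5-fold changes were recovered; depth was not varied.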

Other observations

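The tests that use the column sets, the libraries of fewer than 15000 genes or the place of a single library, and the reading of the number ranges as a rival of the disease, were chosen after the counts of called genes had been seen. The comparison of the control ranges itself and the random splits of its libraries and of all 49 libraries were planned, but the latter were drawn anew after a first draw of 100, whose highest count besides the real one was 12, in place of 1511.

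Many genes differed between OA and Control, and chance, poor libraries and the column sets were each tested as the source. Of 100 splits of the 49 libraries, the real one included, 1 gave as many as 3458 genes (highest other 1511). This argues against chance, as far as 100 splits can show. Splits within sets gave the same rank for the 4787 genes found with the sets as a covariate (1 of 100, highest other 1713). So did splits for the 5569 genes in set 1 (1 of 100, highest other 14) and the 181 genes in set 2 (1 of 100, highest other 0). The count of 181 itself ran from 43 to 1005 without single libraries. Without the 7 libraries of fewer than 15000 genes the count was 4948 and with the sets as a covariate 4787, which argues against either as the whole source. What stays open is a difference between number ranges of the horses that is not disease: controls of 2 ranges differed by 6132 genes, or by 1308 with the sets as a covariate, 2772 in set 1, and 469 with that covariate and without libraries of fewer than 15000 genes, where control 03 alone stands against 12. Since all OA numbers lie between 50 and 76, where no control lies, such a difference and the disease cannot be told apart, and age, sex and breed are untested. A difference in the cell make-up of the preparations is untested too, as the cell type marker scores were not computed.

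Controls 29 to 45 and controls 1 to 16 differ by 6132 genes, and 1 of 100 splits of these 25 libraries gave as many (highest other 1439). This argues against chance, as far as 100 splits can show. A candidate explanation is the column set, since the sets differ by 7228 genes (1 of 100 splits within groups, highest other 1782). The difference between sets 2 and 1 among OA libraries and the difference between controls 1 to 16 and 29 to 45 share no library, and correlated across 13920 genes with r = 0.464. This lay between the bounds of 0.1 and 0.5 set before the test; 100 random splits of the OA libraries into 6 and 14 gave -0.467 to 0.438, r was 0.194 without the libraries of fewer than 15000 genes, and it was 0.3 with controls of set 1 only, so it does not single out the set, whose share in the difference stays open. As the whole source the set is argued against by the 1308 genes left with the sets as a covariate (1 of 100 splits within sets, highest other 662) and the 2772 within set 1 (1 of 100, highest other 83), but the overlap is 3 controls of 1 to 16 in set 1 and control 29 in set 2, 3 of these 4 with fewer than 15000 genes, and without such libraries the 469 genes left with that covariate rest on control 03 against 12; no biological explanation was tested.

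The OA effect differed between sets 1 and 2 for 669 genes. The controls of these sets came mostly from different number ranges, which this comparison cannot separate from the OA effect. Of 100 splits of the set labels within groups, 2 gave as many, the real one and another with 2220, but such splits do not keep the difference between the sets. A further test kept the set and group effects and shuffled the residuals within sets. It used limma with a trend on log2 CPM, not voom, which called 1104 genes in the real order. That count differs from the 669 of edgeR and the 778 of voom. Of 100 shuffles, the real order included, 4 gave as many as 1104 genes (highest other 7263). This lies under the bound of 5 by 1 shuffle, and another shuffle gave 7263 genes, so chance is not excluded. What made the highest counts so high was not tested. For the correlation of 0.502 between the OA fold changes of the sets, 1 of 100 splits of the set 2 libraries gave as large a value (highest other 0.464). This argues against chance only by a small margin and does not exclude it.

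Control 29 lies at the low end of the OA libraries. On a scale where 0 is the mean of the controls and 1 the mean of the OA libraries, over genes called without the library in question, it scored 0.657, above the lowest OA library at 0.575. Besides that library, OA 66, only OA 74 (0.64) scored lower than control 29 among the OA libraries. Controls 09 (0.863) and 80 (0.582) also scored above the lowest OA library. The controls numbered 33 to 45, all in set 1, scored between -0.468 and 0.21. In set 2, which holds control 29, the controls other than 09 and 29 scored between -0.051 and 0.441. Low complexity of the library could account for the place of control 29, as only 14592 genes were detected, but of the other 3 such controls 1 scored at or above the lowest OA library and 06 (0.215) and 07 (-0.024) did not. Placed within its own set it scored 0.451, against 0.374 to 1.744 for the OA libraries of set 2 and 0.909 for control 09. By the rule set before the test, a score at or above the lowest OA library speaks against the sets as the source. The margin was small against the spread of the OA libraries, and the sets were kept open for that reason after the score was seen. For a wrong label or an unrecognised case, the rule, written after the score of 0.657 was seen, also asked that no other control of set 2 reach the lowest OA library. Control 09 did, so that prediction was not met. The opposite prediction, a score of control 29 below that library, was not met either. Low complexity, a difference between the sets of columns and a wrong label or an unrecognised case remain possible. These cannot be told apart from the place of 1 library.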
